A study of Brassica napus with 17 samples.

How the data were processed

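RNA was measured by sequencing in 17 libraries from microspore cultures of Brassica napus, doubled haploid line DH12075, carrying a LEC1-GFP reporter. Per the labels' protocols, late unicellular microspores were sampled untreated at day 0, or were held at 33 °C for 24 hours with or without trichostatin A (TSA), an inhibitor of histone deacetylases. TSA was then removed with the medium, and cultures stayed at 25 °C for 1, 3 or 7 days, which gives the day 2, day 4 and day 8 samples. Per the labels' protocols, RNA was treated with DNase and made into TruSeq libraries. The series design calls the replicates biological.

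The authors deposited raw counts per gene for every library, per the file headers. The aligner, the counting program, the genome build and the annotation are not given in the sources used here. The authors also deposited log2 CPM (counts per 1000000) values for the genes they kept, and, per the file headers, a log2 fold change and a false discovery rate, an adjusted p-value, for 10 comparisons. Limma is the tool named in the submitters' processing notes, with no version. All results here were computed from the raw counts. The authors' log2 fold changes and adjusted p-values were used only for a side by side comparison.

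Each count column was matched to its sample by its title. The table held 101040 gene IDs, of which 12381 had no count in any library and 64330 passed the filterByExpr filter of edgeR. Total counts ran from 2716279 in day 0 replicate 3 to 31407037 in heat plus TSA day 4 replicate 1. The level that 3 counts stand for ran from 0.0809 to 0.787 CPM, so a gene under that level in a library is below what its depth resolves. Levels are given as CPM with TMM-scaled library sizes. They cover counting error and the spread between the replicates at hand, not errors shared by a whole group.

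The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, robust dispersion and 1 coefficient per group over all 17 libraries. It was two-sided, with Benjamini-Hochberg adjustment over the 64330 genes of a comparison. A gene was called at an adjusted p under 0.05. The SE of a log2 fold change is its absolute value divided by the square root of the F statistic of this test. It restates the test and was not estimated separately. The number that also changed by at least 1 log2 unit is given beside it. The 8 comparisons, this test and most alternatives were fixed before the data were examined. On simulated counts for the comparison of heat plus TSA with heat alone at day 2, run on 64330 genes, the test recovered 34% of genes changed by 1 log2 unit and 87% of those changed by 2. Of its calls 4.72% were false. For day 8 against day 0 the shares recovered were 10% and 83%, with 5.1% false. For the difference between the day 4 and day 2 effects of TSA they were 3% and 53%, with 6.67% false. Each simulation changed only 100 genes by 1 log2 unit and 100 by 2, and 127, 98 and 60 genes were called. Far more genes were called in the data, which moves the cutoff of the adjustment, so these shares need not hold there.

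The gene IDs are those of the count table. The reference used here, assembly Da-Ae, listed 3347 of them as symbols, and gave another name for only 2, KCP1 and TR1. The files do not pair the IDs with Arabidopsis genes. The 15 gene lists fixed beforehand could therefore not be tested, nor could the rule written for named genes be applied. IDs are named instead by a rule written after the counts had been read: per comparison, the 2 rising and the 2 falling genes with the lowest p among those called. A mean of at least 10 CPM in a compared group and at least 10 counts in the lower group were required. Between 2 groups the libraries also had to be without overlap, which chance gives for 10% of genes at 3 against 3. KCP1 and TR1 are reported whatever their test. B. napus carries A and C subgenomes with near-identical gene copies, and how reads shared between copies were counted is not given, so the level of a single copy is uncertain.

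To compare the number of genes detected, each library was thinned to 2500000 counts by random draws with replacement, in proportion to its counts. Such draws miss genes of a shallow library, so some effect of the original depth remains. Day 0 replicate 3, with 2716279 counts, had 50892 genes with a count before and 47582 after the draw. As alternatives, chosen after the result was seen, libraries were thinned to 2000000 or 1000000 counts, a minimum of 10 counts was set, or the 385 genes among the 100 most abundant of any group were left out before thinning to 2000000 counts, with and without the minimum of 10 counts. Differences between 3 and 3 libraries were tested with exact two-sided permutation tests, and over both days with labels permuted within each day. A gene was said to be switched on where its call came with a mean of at least 1 CPM in one group and under 0.1 CPM in the other.

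Neighbouring genes were compared in 1900 windows of 30 genes, at steps of 15, over 28930 genes with a mean of at least 1.5 log2 CPM. Order came from the number in the gene ID. For the 2990 IDs with both a chromosome in the ID and an entry in the reference, 91.4% lay on the same chromosome there, and the absolute rank correlation of ID number and reference order was 0.779 to 0.977. For each library the deviation from the other replicates of its group was set against 1000 shuffles of gene order, with Benjamini-Hochberg adjustment over the 17 libraries. In simulated data on 28930 genes, 4 of 4 windows inside a lowered block were found and 0 outside it. This window analysis was chosen after the libraries had been seen to differ.

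Alternatives were RLE and upper-quartile scaling, no scaling beyond library totals, no filter, a filter of at least 1 CPM in at least 3 libraries, the Wald test of DESeq2 1.42.0, voom in limma 3.58.1, a fit on the compared groups alone, the replicate number as a block, and each replicate left out in turn. Also run, after the data had been seen, were fits without 3 libraries together (replicate 1 of heat-only day 2 and of heat-only day 4, and day 0 replicate 3) and without the genes of the chromosome segments described with the results. A stricter cutoff on the main fit, a change of at least 1 log2 unit, was also counted as an alternative. No library was left out of the main test.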

Results

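The 17 libraries fell into 6 groups. There were 3 libraries of untreated microspores at day 0, 3 of heat-stressed cultures at day 2 and 3 at day 4. With TSA added to the heat stress there were 3 at day 2, 3 at day 4 and 2 at day 8. Per the labels, heat alone served to induce embryogenesis, and heat with TSA to induce callus. The TSA dose was 0.5 µM at day 2 and 0.05 µM at day 8. For the day 4 cultures the sample titles give 0.5 µM and the treatment field 0.05 µM, so their dose is open. Total counts per library were 27496445, 20851018 and 2716279 at day 0. They ran from 17845967 to 28680600 in heat-only day 2 and from 9360060 to 24406600 in heat-only day 4. With TSA they ran from 13707782 to 25189108 at day 2 and from 15275408 to 31407037 at day 4, and were 14142177 and 21839207 at day 8. The labels place day 0, TSA day 2 and TSA day 8 in 1 sequencing run, and name no run for the other groups.

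Libraries of cultures with TSA stood apart from heat-only libraries at days 2 and 4. The first principal component of log2 CPM held 46.3% of the variance and the second 28.4%. Across genes, which are not independent replicates, heat-only and TSA libraries of day 4 correlated at 0.549 to 0.642. TSA libraries of day 2 and day 4 correlated at 0.926 to 0.967, and heat-only libraries of those days at 0.853 to 0.925.

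**Figure D1:**
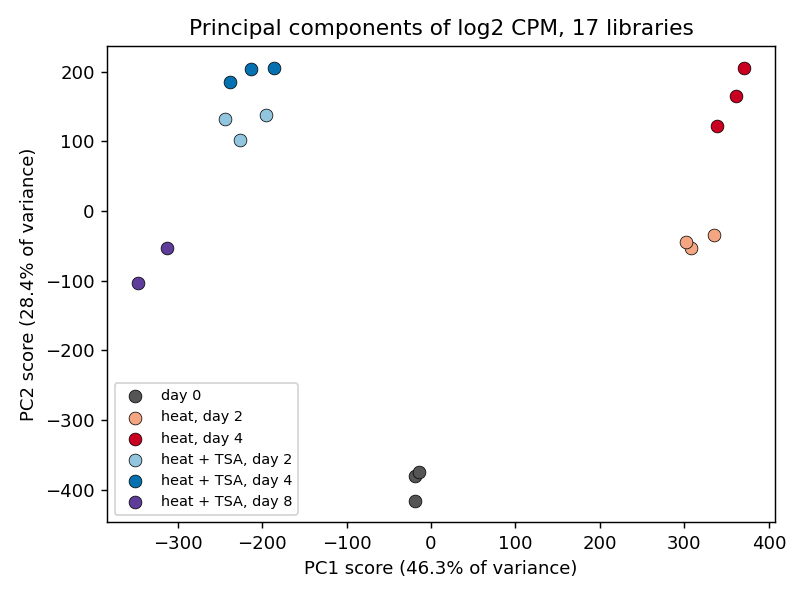
Scores of the 17 libraries on the first and second principal components of log2 CPM, 1 point per library, coloured by group. Heat-only libraries lie on the right, TSA libraries on the left and day 0 libraries at the bottom, with 46.3% of the variance along the horizontal axis and 28.4% along the vertical axis.

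The first comparison asks what adding TSA to heat stress changed by day 2. BnaC06g38220D rose from 1.35 ± 0.0743 CPM (SD, n = 3) in heat-only cultures to 33.5 ± 3.25 CPM (SD, n = 3) with TSA. BnaCnng06690D rose from 8.19 ± 0.684 to 123 ± 12.4 CPM (SD, n = 3 each). BnaC02g27940D fell from 92.6 ± 6.60 CPM to 0.573 ± 0.153 CPM, and BnaA06g18310D from 31.2 ± 2.05 CPM to 0.234 ± 0.0498 CPM (SD, n = 3 each). Their log2 fold changes were 4.63 ± 0.18, 3.91 ± 0.159, -7.27 ± 0.225 and -7.06 ± 0.246 (SE). The adjusted p-values in that order were 4.13e-11, 4.96e-11, 1.72e-11 and 2.84e-11 (edgeR quasi-likelihood test, Benjamini-Hochberg). Levels at day 0 were 3.35, 21.4, 1.44 and 0.426 CPM, so both falling genes were far below their heat-only level before culture as well. In all, 42701 of 64330 genes were called, 22363 higher and 20338 lower with TSA, and 33449 of them by at least 1 log2 unit. With scaling by library totals alone, 72.8% of calls were higher instead of 52.4%. No run is named for the heat-only libraries, so a difference in run as part of this contrast was not excluded; TSA day 4, with no run named either, had BnaC02g27940D at 1.17 CPM against 78.7 CPM in heat-only day 4.

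Among these genes, 1809 were switched on with TSA at day 2, at 1 CPM or more against under 0.1 CPM in heat-only cultures, and 1584 were switched off. The limit of 0.1 CPM lies under the level of 3 counts in heat-only day 2 libraries, 0.122 to 0.223 CPM. Both sets were then followed in libraries not used to pick them, though some same-numbered libraries of days 2 and 4 deviated together. Of the 1809, 1600 (88.4%) were called higher with TSA at day 4 and 0 lower. Of the 1584, 1562 (98.6%) were called lower at day 4 and 0 higher. Among all 64330 tested genes, 25947 were called higher and 17566 lower at day 4. At day 0, 1314 of the 1809 and 1156 of the 1584 had a mean under 0.1 CPM, so most genes of both sets were near or below detection before culture. With TSA at day 8, 526 of the 1809 were at 1 CPM or more and 824 under 0.1 CPM, and 1339 of the 1584 were under 0.1 CPM.

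The same comparison was made at day 4. BnaC07g20340D rose from 4.34 ± 1.27 CPM in heat-only cultures to 398 ± 35.2 CPM with TSA, and BnaA05g16450D from 8.34 ± 0.537 CPM to 80.3 ± 3.03 CPM (SD, n = 3 each). BnaA05g11140D fell from 116 ± 10.5 CPM to 1.51 ± 0.159 CPM, and BnaA09g56870D from 96.8 ± 9.46 CPM to 3.86 ± 0.0333 CPM (SD, n = 3 each). The log2 fold changes were 6.48 ± 0.305, 3.26 ± 0.152, -6.25 ± 0.189 and -4.65 ± 0.157 (SE). The adjusted p-values were 1.06e-10, 9.92e-11, 1.16e-11 and 1.79e-11 (edgeR quasi-likelihood test, Benjamini-Hochberg). BnaC07g20340D was at 0.403 CPM with TSA at day 8, and BnaA05g16450D at 16.1 CPM. In all, 43513 genes were called, 25947 higher and 17566 lower with TSA, and 35883 of them by at least 1 log2 unit. Of the genes called higher at day 2, 17861 were also called higher at day 4, where independent lists would share 9020. Of those called lower, 14469 were also called lower, where independent lists would share 5554. Across all genes the fold changes of the 2 days correlated at 0.866, and genes are not independent replicates. With scaling by library totals 80.8% of calls were higher instead of 59.6%, and the median fold change of all genes was 1.58 instead of 0.44 on the log2 scale. The conflicting TSA dose in the labels applies to this comparison.

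Whether the TSA effect differed between the days was tested as the day 4 effect minus the day 2 effect. In this contrast only TSA day 2 has a named run, and the TSA dose of day 4 is open, so neither run nor dose was excluded. BnaC03g56330D had the lowest p. Its level was 53.9 CPM without and 31 CPM with TSA at day 2, and 14.8 CPM without and 49.7 CPM with TSA at day 4, a difference of effects of 2.54 ± 0.192 (log2, SE). For BnaC08g35650D the difference was 2.71 ± 0.234: heat-only cultures went from 67.2 ± 7.73 to 9.42 ± 1.54 CPM (SD, n = 3 each) while TSA cultures were at 10.8 and 9.93 CPM. BnaA06g30840D (-4.01 ± 0.292) was at 45.4 CPM with TSA at day 2 and 12.6 CPM at day 4, against 1.56 and 6.88 CPM in heat-only cultures. BnaCnng01270D (-3.63 ± 0.347) was at 40.3 and 37.1 CPM with TSA, and at 0.465 and 5.45 CPM without. The adjusted p-values of these 4 were 1.52e-05, 5.38e-05, 1.52e-05 and 1.19e-04 (edgeR quasi-likelihood test, Benjamini-Hochberg). In all, 15920 genes were called, 12781 of them with a difference of at least 1 log2 unit. There were 1009 genes called lower with TSA at day 2 and higher at day 4, and 188 the other way. These counts depended on the scaling too: they were 406 and 381 with RLE factors, 526 and 294 with upper-quartile factors, and 841 and 110 with library totals. The balance of directions depended on the scaling: 57.6% of calls were higher with TMM, 31.8% with RLE factors, 45% with upper-quartile factors, 81.4% with library totals and 32.3% with DESeq2. Without heat-only day 2 replicate 2 the count was 9859, and without heat-only day 4 replicate 2 it was 9818.

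A small set of genes made up much of the RNA in heat-only cultures. The 100 most abundant genes of heat-only day 2 held 22.7% ± 3.81 of counts there (SD, n = 3). In heat-only libraries of day 4, which were not used to pick them, they held 34.8% ± 0.907 (SD, n = 3), and with TSA at day 4 1.03% ± 0.218 (SD, n = 3). The difference at day 4 was -33.7 percentage points (exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow). These genes held 1.43% ± 0.165 of counts at day 0 (SD, n = 3) and 0.63% ± 0.058 with TSA at day 8 (SD, n = 2). The 100 most abundant genes of TSA day 2 held 10.1% ± 0.769 there, 12.7% ± 0.777 with TSA at day 4 and 1.40% ± 0.0451 in heat-only day 4 (SD, n = 3 each). They held 3.61% ± 0.495 with TSA at day 8 (SD, n = 2).

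More genes were detected in cultures with TSA. With every library thinned to 2500000 counts, 58294 ± 216 genes had a count with TSA at day 2 and 51590 ± 678 in heat-only cultures (SD, n = 3 each). At day 4 the numbers were 57158 ± 250 and 49743 ± 1170 (SD, n = 3 each). Day 0 had 50213 ± 2280 (SD, n = 3), lowered by its shallow replicate 3 at 47582, and TSA day 8 had 50430 ± 292 (SD, n = 2). Each day's difference, 6704 and 7414 genes, reached the smallest exact two-sided permutation p of 0.1. With labels permuted within both days the exact two-sided permutation p was 0.005, the smallest possible, and 0.005 after Benjamini-Hochberg adjustment over 2 measures. The other measure was the share of counts in a library's own 100 most abundant genes, which differed by -12.6 percentage points at day 2 and -23.0 at day 4, with the same exact permutation p. Permuting each day apart takes the libraries of both days as independent. Some same-numbered libraries deviated together across days, at 0.295 for heat-only replicate 1 and 0.498 for TSA replicate 3. The p over both days may therefore be too low. All 6 TSA libraries of these days lay above all 6 heat-only ones in genes detected. By group means with TMM scaling, 45663 genes were at 1 CPM or more with TSA at day 2 and 42441 in heat-only cultures. At day 4 they numbered 45834 and 44234. The gap was smaller by that measure, so its size depends on the measure and the scaling. No heat-only library is labelled with the named run, so no value of this difference within that run can be given.

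**Figure D2:**
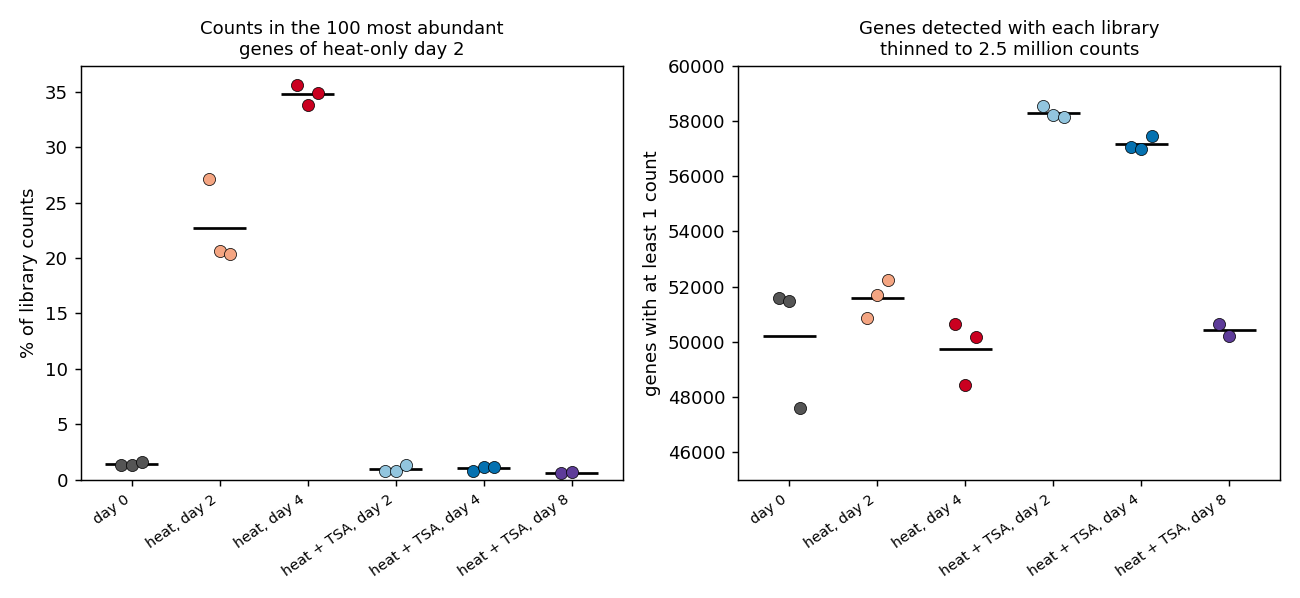
Left, percent of library counts in the 100 most abundant genes of heat-only day 2. Right, genes with at least 1 count after thinning to 2500000 counts (axis not starting at 0); points are libraries and lines group means, with 34.8% against 1.03% at day 4 on the left and 57158 against 49743 genes on the right.

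Heat-only cultures of day 2 were compared with untreated microspores of day 0. BnaC03g53730D rose from 0.471 ± 0.0481 CPM to 24.2 ± 1.71 CPM, and BnaA09g31690D from 0.858 ± 0.128 CPM to 46.9 ± 4.1 CPM (SD, n = 3 each). BnaC08g29670D fell from 102 ± 4.44 CPM to 0.777 ± 0.074 CPM, and BnaA06g04210D from 415 ± 104 CPM to 12.1 ± 1.47 CPM (SD, n = 3 each). Their log2 fold changes were 5.72 ± 0.187, 5.73 ± 0.203, -7.04 ± 0.232 and -5.10 ± 0.208 (SE). The adjusted p-values were 2.38e-11, 3.34e-11, 2.38e-11 and 8.79e-11 (edgeR quasi-likelihood test, Benjamini-Hochberg). In all, 36294 genes were called, 19992 higher and 16302 lower, 27053 of them by at least 1 log2 unit. There were 2640 genes switched on from under 0.1 CPM and 199 switched off. With library totals alone 31.5% of calls were higher instead of 55.1%. Day 0 is labelled with the named run and heat-only day 2 with none, so a difference in run was not excluded. No culture without heat is among the samples, so heat and time in culture cannot be told apart here.

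Genes that changed from day 0 to heat-only day 2 tended to differ the other way with TSA at day 4, a comparison that shares no library with the first. Across genes the fold changes correlated at -0.527. Heat-only cultures enter these comparisons with opposite sign, and their libraries of days 2 and 4 correlated at 0.853 to 0.925. Opposite directions can therefore arise without TSA reversing the response to heat and culture. The numbers for independent lists are no measure of chance here. Of the 19992 genes that rose with heat and culture, 11468 (57.4%) were called lower with TSA than without at day 4, where independent lists would share 5459, and 4185 were called higher. Of the 16302 that fell, 10388 (63.7%) were called higher with TSA, where independent lists would share 6575, and 1419 lower. Under the RLE, upper-quartile and library-total scalings these shares were 61%, 59% and 51.4% of the rising genes and 57.3%, 62.9% and 81.8% of the falling genes.

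From day 2 to day 4, heat-only cultures changed in 29185 genes, 20522 of them by at least 1 log2 unit, and TSA cultures in 4114, of which 3285 by as much. In heat-only cultures BnaA10g23900D rose from 4.78 ± 0.551 CPM to 40.6 ± 9.29 CPM, and BnaC09g32980D from 0.725 ± 0.106 CPM to 32.2 ± 12.2 CPM (SD, n = 3 each). BnaC06g37940D fell from 16.7 ± 0.799 CPM to 1.47 ± 0.114 CPM (SD, n = 3 each), and BnaC08g35650D fell by 2.83 ± 0.173 on the log2 scale (SE). In TSA cultures BnaA06g35420D rose from 11.5 ± 3.06 CPM to 129 ± 1.86 CPM, and BnaCnng15630D from 0.131 ± 0.126 CPM to 27.6 ± 5.01 CPM (SD, n = 3 each). BnaC01g07950D fell from 34.2 ± 6.34 CPM to 5.29 ± 0.207 CPM, and BnaC09g42630D from 19.7 ± 2.56 CPM to 2.04 ± 0.319 CPM (SD, n = 3 each). The adjusted p-values of the 4 heat-only changes were 1.98e-06, 1.98e-06, 4.64e-07 and 4.64e-07, and those of the 4 TSA changes 1.99e-06, 3.17e-05, 1.01e-06 and 1.93e-06 (edgeR quasi-likelihood test, Benjamini-Hochberg). BnaC09g32980D was already at 49.1 CPM with TSA at day 2 and at 116 CPM at day 4. The lists shared 1645 rising genes, where independent lists would share 576, and 591 falling genes, where they would share 352. The 15920 genes of the test between days are also those whose change over time differed with TSA, since the contrast is the same. A part of run or of the open dose in that difference was not excluded. The same holds for the change of TSA cultures from day 2 to day 4. In heat-only cultures 48.9% of calls were higher with TMM, 66.9% with RLE factors, 67.4% with DESeq2 and 21.5% with library totals. In TSA cultures 63.1% were higher with TMM, 48% with upper-quartile factors and 41.1% with library totals. Leaving out single libraries lowered the TSA count to 1342 (TSA day 2 replicate 1), 2361 (TSA day 4 replicate 1) and 2097 (TSA day 4 replicate 2).

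The day 8 cultures, all with TSA, were compared with day 0 and with TSA day 4. BnaA06g11670D rose from 0.762 ± 0.225 CPM at day 0 (SD, n = 3) to 86.9 ± 2.94 CPM at day 8 (SD, n = 2), and BnaC08g27320D from 2.47 ± 0.183 CPM (SD, n = 3) to 187 ± 55.6 CPM (SD, n = 2). BnaC03g66770D fell from 42.0 ± 1.84 CPM (SD, n = 3) to 0.32 ± 0.0741 CPM (SD, n = 2). BnaA04g29020D, at 40.3 CPM on day 0 and 204 CPM in heat-only cultures of day 2, was at 0.369 CPM. From TSA day 4 to day 8, BnaA04g29230D rose from 1.25 ± 0.254 CPM (SD, n = 3) to 89.2 ± 11.8 CPM (SD, n = 2), and BnaC07g04210D from 1.73 ± 0.151 CPM (SD, n = 3) to 146 ± 38.6 CPM (SD, n = 2). BnaA07g21200D fell from 27.5 ± 2.59 CPM to 0.213 ± 0.0762 CPM, and BnaA02g33880D from 32.6 ± 0.621 CPM to 0.213 ± 0.0762 CPM (SD, n = 3 and n = 2). Adjusted p-values were 1.21e-11, 1.21e-11, 1.21e-11 and 2.40e-11 against day 0, and 5.94e-11, 5.94e-11, 5.94e-11 and 9.18e-11 against day 4 (edgeR quasi-likelihood test, Benjamini-Hochberg). Against day 0, 37396 genes were called, 18630 higher and 18766 lower, 30353 by at least 1 log2 unit, with 3191 switched on and 3009 switched off. Against TSA day 4, 37574 were called, 15047 higher and 22527 lower, 29354 by at least 1 log2 unit, with 983 switched on and 3185 switched off. No heat-only culture of day 8 is among the samples, so the effect of TSA cannot be told apart from time, and the dose differs from that of day 2 as well. TSA day 8 is labelled with the named run and TSA day 4 with none, so a difference in run was not excluded between them.

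**Figure D3:**
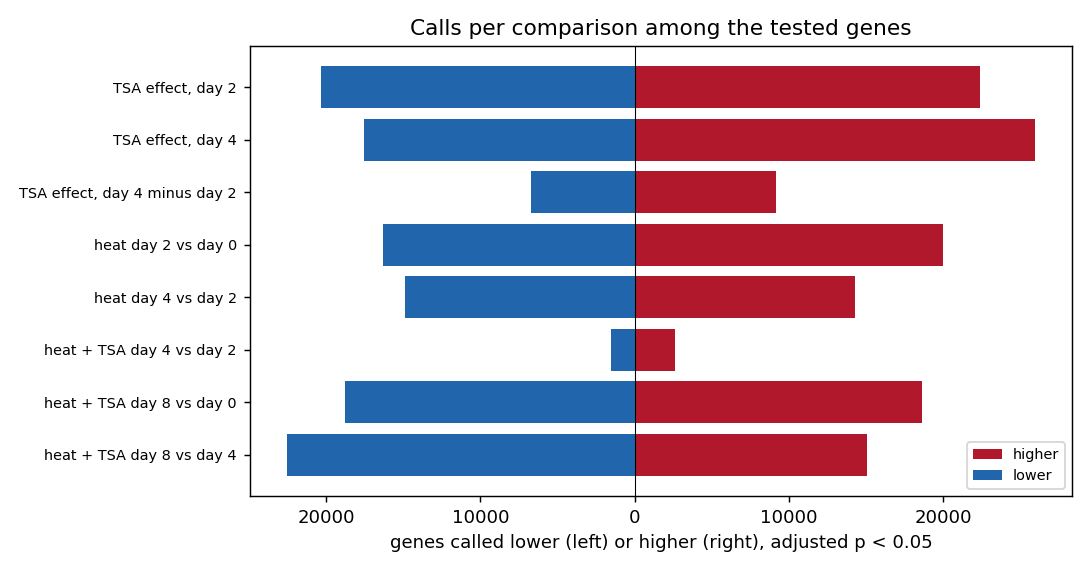
Number of genes called lower (left) and higher (right) in each of the 8 comparisons, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05. The longest bar is 25947 genes, higher with TSA at day 4, and the change from day 2 to day 4 with TSA has the fewest calls, 4114.

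KCP1 (BnaA02g32290D), one of the 2 genes with a name in the reference, was low in heat-only cultures and higher with TSA. Its level was 1.58 ± 0.528 CPM at day 0, 0.165 ± 0.0167 CPM in heat-only day 2 and 0.269 ± 0.198 CPM in heat-only day 4 (SD, n = 3 each). With TSA it was 1.86 ± 0.156 CPM at day 2, 2.91 ± 0.628 CPM at day 4 (SD, n = 3 each) and 5.54 ± 0.851 CPM at day 8 (SD, n = 2). The TSA effect was 3.43 ± 0.38 at day 2 and 3.23 ± 0.40 at day 4 (log2, SE), with adjusted p-values of 6.53e-07 and 2.40e-06 (edgeR quasi-likelihood test, Benjamini-Hochberg). The heat-only levels lie near or under those that 3 counts give in these libraries, 0.122 to 0.223 CPM at day 2 and 0.248 to 0.529 CPM at day 4, so the size of both fold changes is uncertain. TR1 (BnaCnng15100D) was at 9.99 ± 1.93 CPM in heat-only day 2 and 9.82 ± 1.28 CPM with TSA (SD, n = 3 each), a log2 fold change of -0.02 ± 0.22 (SE), and was not called in any of the 8 comparisons. At day 4 its log2 fold change of -0.39 with TMM passed the threshold as -0.66 with RLE factors and as 0.79 with library totals. The median of all genes moved by about as much, from 0.44 to 0.18 and to 1.58, so the change of sign follows the shift shared by all genes. Without heat-only day 4 replicate 1 or 3 it passed as -0.86 or -0.70.

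Runs of neighbouring genes differed between libraries of the same group. In heat-only day 2 replicate 1, 64 of 1900 windows of 30 genes deviated from the other replicates beyond the 95% limit of shuffled gene order, and in heat-only day 4 replicate 1, 42 did. Replicates 2 and 3 had 49 and 58 such windows at heat-only day 2, and 18 and 40 at heat-only day 4. With TSA the number ran from 7 in day 4 replicate 2 to 62 in day 4 replicate 3. A shift in 1 library also enters the deviations of its other replicates. Among heat-only libraries the largest deviation was -1.77 log2 units on chromosome C04, in day 2 replicate 1 (permutation p = 0.001, the smallest that 1000 shuffles give, and 0.0013 after Benjamini-Hochberg adjustment over 17 libraries). The largest deviations between the day 8 libraries were 1.99 and -1.99, on A07. In the 3 day 0 libraries 0 windows passed the limit, with permutation p-values of 0.4, 0.5 and 0.4 for their largest deviations. At the start of C04, IDs numbered 10 to 7130, the median of 135 genes over day 0 was -0.42 and -0.64 in heat-only replicate 1 of days 2 and 4. It was 0.92 and 0.90 in replicates 2 and 3 of day 2, and 0.89 and 1.03 in those of day 4. TSA libraries were at -0.71, -0.64 and -0.66 on day 2, at -0.77, -0.88 and -0.51 on day 4, and at -2.17 and -2.06 on day 8. On A05, IDs 70 to 2930, heat-only replicate 1 was at 0.50 and 0.36 on days 2 and 4, while replicates 2 and 3 lay at -0.36 and -0.40 on day 2 and at -0.37 and -0.32 on day 4. On C02, IDs 30550 to 44250, replicate 3 of TSA day 2 and of TSA day 4 stood at -0.48 and -0.47, and the day 8 libraries at -1.06 and -1.07.

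**Figure D4:**
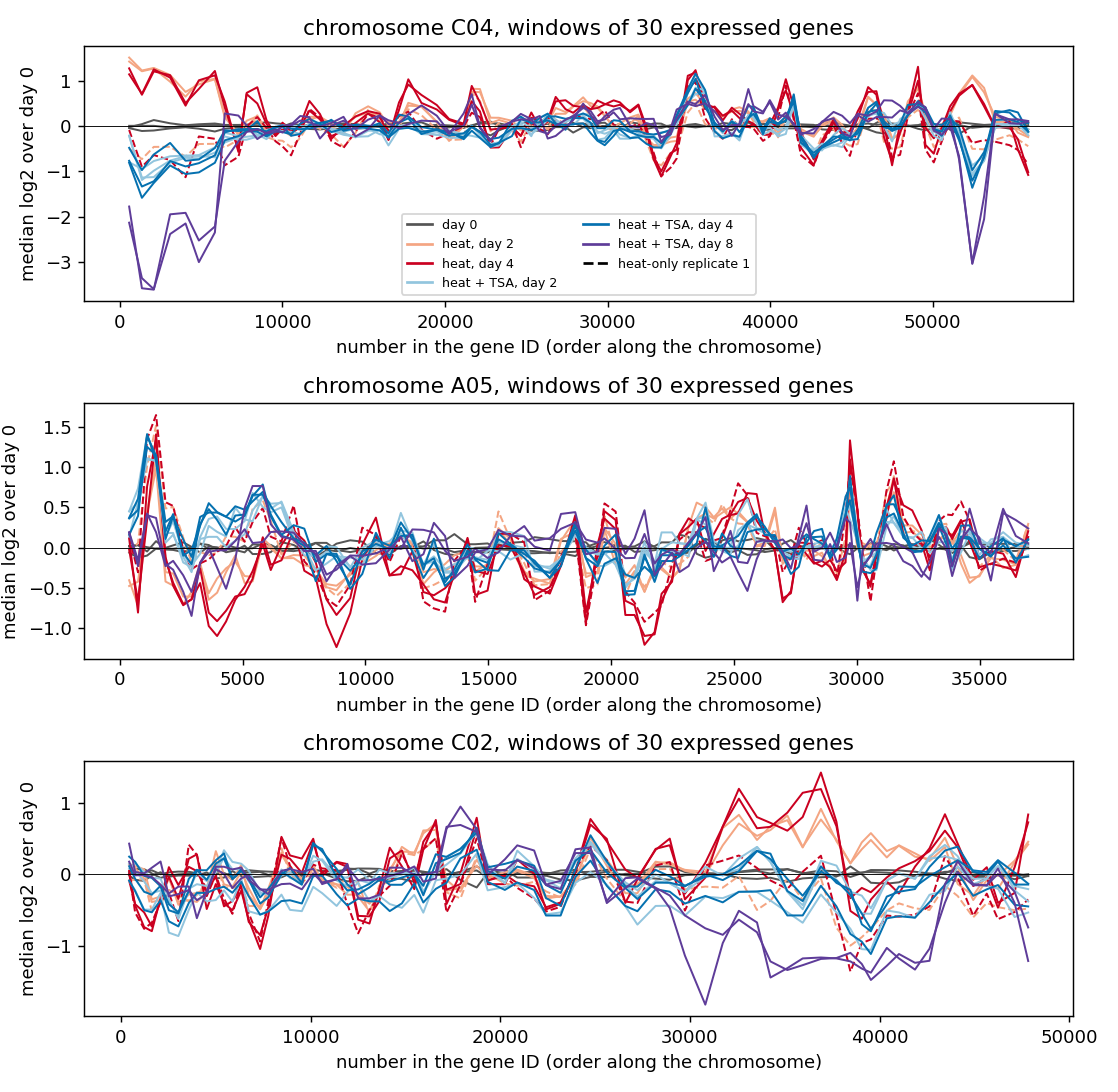
Median log2 level over day 0 in windows of 30 expressed genes along chromosomes C04, A05 and C02, ordered by the number in the gene ID, 1 line per library. At the start of C04 the day 8 libraries lie lowest, with segment medians of -2.17 and -2.06, and the dashed heat-only replicate 1 lines lie apart from replicates 2 and 3.

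Of 386 genes tested at the start of C04, 195 were called lower and 67 higher with TSA at day 2, with a median log2 fold change of -1.09. The TSA libraries of day 2 lay at -0.71 to -0.64 over day 0 there, and heat-only replicate 1 at -0.42. Heat-only replicates 2 and 3 of day 2 were at 0.92 and 0.90. A TSA effect on these genes therefore cannot be told apart from the difference between replicates. At day 8 against TSA day 4, 235 were called lower and 29 higher, with a median of -2.85. In the C02 segment 343 of 705 genes were called lower and 57 higher at day 8 against TSA day 4. By its ID number BnaA10g23900D lies in a segment of A10, IDs 23820 to 25510, that differed between the day 8 libraries. BnaC02g27940D and BnaA05g11140D lie outside the segments of C02 and A05.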

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

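The test of scaling as a cause of the balance of directions, and scaling by library totals, were chosen only after the results had been seen; the regrouping of samples was planned. What marked these results out is that the effect of TSA differed between day 4 and day 2 by a test of the difference itself (edgeR quasi-likelihood, Benjamini-Hochberg).

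The difference was called for 15920 genes. Among them 1009 were called lower with TSA at day 2 and higher at day 4, and 188 the other way; with RLE factors the calls in opposite directions were 406 and 381, so the imbalance depended on the scaling. The difference of effects on the log2 scale was 2.54 for BnaC03g56330D, 2.71 for BnaC08g35650D, -4.01 for BnaA06g30840D and -3.63 for BnaCnng01270D. For genes named for the TSA effect of a single day it was -1.28 for BnaC06g38220D, -0.80 for BnaCnng06690D, 1.2 for BnaC02g27940D and -1.31 for BnaA05g11140D; for these the effect on both days had the same direction. Of these, BnaC02g27940D was no longer past the threshold without heat-only day 2 replicate 2 (0.83) or 3 (0.87), or without heat-only day 4 replicate 2 (0.91) or 3 (0.89), and BnaCnng06690D not with library totals (-0.32).

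Regrouping does not exclude chance for the count, and it cannot decide on it. Of 30 splits of the 12 libraries, 4, the real one included, called at least as many genes. The highest of the other splits called 25949. All 3 of the other splits with as many calls kept the TSA and heat-only libraries of day 2 together and mixed those of day 4. Their contrast took up the TSA effect of day 2, so their counts are no measure of chance. Further splits that kept day 2 together called only 332 and 1847 genes, and a split that kept day 4 together called 6034. Keeping day 2 together therefore did not by itself give as many calls, and the mix of day 4 libraries enters the contrast too. The 23 splits that kept neither day's groups together called 0 genes with the edgeR quasi-likelihood test, and at most 2075 at an unadjusted p under 0.05. Mixing TSA and heat-only libraries puts their difference into the spread and lowers the calls, so these low counts do not decide on chance.

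With TMM scaling 57.6% of the called genes had a higher TSA effect at day 4 than at day 2, and this balance may come from the scaling of the libraries. With RLE factors 31.8% of calls were higher. These factors move the difference of all genes together, with a median of -0.26 instead of 0.08 on the log2 scale, so this share follows from that shift and does not say which scaling is right. Scaling and a biological shift in the balance of directions, with day or with the open TSA dose of day 4, therefore cannot be told apart. A difference in run, named only for TSA day 2 in this contrast, was not excluded either. The gene count was 15111 with RLE factors.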

How the results depend on the processing

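Alternatives chosen only after the data had been seen were scaling by library totals, leaving out 3 doubted libraries together, leaving out the segment genes, and every alternative for genes detected and for abundant genes. For each of the 8 counts of called genes, 12 of 12 alternatives other than single left-out libraries lay within 1.5 times the value reported. The 12 include a stricter cutoff on the main fit, a change of at least 1 log2 unit, which gave the lowest value for each count. The ranges of these were 33449 to 43830 for TSA at day 2, 35883 to 51177 for TSA at day 4, 12781 to 21441 for the difference of effects, 27053 to 40437 for heat-only day 2 against day 0, 20522 to 35710 for heat-only day 4 against day 2, 3285 to 5768 for TSA day 4 against day 2, 30353 to 38294 for day 8 against day 0 and 29354 to 40440 for day 8 against TSA day 4. Leaving out single libraries gave 38306 to 40994, 37745 to 41625, 9818 to 16751, 30799 to 35088, 22000 to 28514, 1342 to 3250, 33230 to 36655 and 32633 to 34683 in that order. A day 8 library left alone is assumed to vary like the other groups. The difference of effects moved most without heat-only day 2 replicate 2 (9859) or heat-only day 4 replicate 2 (9818), and TSA day 4 against day 2 without TSA day 2 replicate 1 (1342), TSA day 4 replicate 1 (2361) or replicate 2 (2097); fewer samples enter these fits, and the cause was not tested further. The replicate number as a block gave 42707, 43520, 15683, 36131, 29110, 4475, 37159 and 36834 calls and ended no result. The labels tie numbers 1, 2 and 3 to lanes 4, 5 and 6 of the named run in day 0, TSA day 2 and TSA day 8. Libraries of 1 lane correlated in their deviations at 0.042, 0.075 and 0.076 (day 0 and TSA day 2), 0.106 and -0.027 (day 0 and day 8) and 0.035 and -0.123 (TSA day 2 and day 8). The numbers were not taken to pair the samples, since not all same-numbered libraries deviated together: those of days 2 and 4 correlated at 0.295, 0.08 and 0.227 in heat-only and at 0.276, 0.079 and 0.498 in TSA cultures. Replicates 1 and 3 of both deviated together across days; replicate 2 correlated better with another number (0.196 and 0.435). The filter also moved the balance of directions, to 30% higher calls for the difference of effects with at least 1 CPM in 3 libraries, 43% without a filter, and for heat-only day 4 against day 2 to 66.2% and 59.4%. Library totals put the median log2 fold change of all genes at 0.72, 1.58, 0.56, -0.57, -0.70, -0.17, -0.10 and -0.13, in the order given, against 0.06, 0.44, 0.08, 0.07, 0, 0.04, 0 and -0.29 with TMM; RLE factors gave 0.18 for TSA at day 4, -0.26 for the difference of effects and 0.28 for heat-only day 4 against day 2. Fold changes are relative to the TMM values.

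Of single IDs, 696 values kept their direction and their side of the threshold, 5 lost the threshold, 6 gained it and 12 reversed. All reversals and gains were of TR1, which was not called in the values reported. At day 2 its log2 fold change became 0.0707 (RLE), 0.20 (upper quartile), 0.65 (library totals), 0.11 (no filter), 0.0561 (strict filter), 0.0711 (DESeq2) and 0.16 (3 libraries out), and ran from -0.13 to 0.16 with single libraries left out; at day 4 it became 0.79 (library totals). The library-total values passed the threshold as higher, while at day 4 TR1 passed as lower with RLE (-0.66), the strict filter (-0.71), DESeq2 (-0.66), 3 libraries out (-0.86), and without heat-only replicate 1 (-0.86) or 3 (-0.70). The values under RLE, upper-quartile and library-total scaling and DESeq2 moved about as far as the median of all genes; the cause of the others was not tested. Gene list tests and their alternatives were not run, since the IDs pair with no list. Depth limits genes under about 0.787 CPM in day 0 replicate 3.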

Other observations

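The tests of segments and of genes detected were chosen only after these patterns had been seen; the regrouping of samples was planned.

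Genes of the A subgenome were called higher with TSA somewhat more often than genes of the C subgenome. At day 2 it was 36.5% of 30665 A genes and 33.2% of 33471 C genes, and at day 4 42.3% and 38.6%. C04 had the fewest genes higher at day 2, 28.8%, against 38% on A05. Both hold segments that differed between replicates and feed these shares: 67 genes were higher and 195 lower at C04 IDs 10 to 7130, 37 and 88 at C04 IDs 51110 to 54170, and 104 and 41 at A05 IDs 2980 to 6100. These shares were not tested, and homoeologous copies can share reads. The authors' own adjusted p-values cover 63481 of the genes tested here. Of these, 40877 were called in both for TSA at day 2 and 41017 at day 4, with 0 of opposite sign. The authors' table has 45506 and 43402 genes under 0.05 among its 68491. Both rest on the same libraries, so this is no independent evidence. For heat-only day 4 against day 2 the authors had 16398 genes higher and 11073 lower, against 14267 and 14918 here.

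The 2 day 8 libraries differed from each other along whole segments. On A07, IDs 1870 to 4420, replicate 1 was at 0.88 and replicate 2 at -0.75 log2 units over day 0. On C06, IDs 39280 to 41710, they were at -0.97 and -0.23, and on C09, IDs 47140 to 51110, at -0.10 and -0.81. On the C09 segment the other libraries lay between -0.20 and 0.03.

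Segments differed between libraries of the same group, and a candidate explanation is that they were present in different copy number in the starting material. Of the 14 segments found in heat-only day 2 replicate 1, 14 deviated in the same direction in heat-only day 4 replicate 1, a library not used to find them. The first library was picked after its deviation had been seen. Only direction was counted: the lowered segments deviated by -0.12 to -1.36 in the second library, where the limit for a window was 0.56. Any other state shared by both libraries would give the same directions, so they do not single out copy number. Noise or depth of single libraries is argued against by the shuffled gene order (permutation p = 0.001). At the start of C04, heat-only day 4 replicate 1 stood at -1.36 log2 units against the other replicates. No heat-only library received TSA, so the labels alone set TSA aside as the cause there, and the value does not test it. For the day 8 libraries, -1.40 log2 units below TSA day 4 in that segment, day, dose and starting material cannot be told apart, since no day 8 culture without TSA is among the samples. Whether the genome itself differs was not measured here.

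More genes were detected in TSA than in heat-only libraries, and 4 technical explanations were tested. Depth as the whole cause is argued against by the difference at equal depth, at least 6704 genes on either day, and the few abundant genes as the whole cause by the differences that stayed without them, 5581 against 6708 with all genes at the same 2000000 counts at day 2, and 4917 against 7745 at day 4; they may account for part of it. Genes with 10 counts or more also differed, by at least 4329 once the abundant genes were left out. The gap was thus not confined to genes with few reads. That count leaves out genes seen with few reads, so a part of single stray reads, such as from genomic DNA, was not excluded. The run named for TSA day 2, as the whole cause, is argued against by TSA day 4, which exceeded heat-only day 4 by 7414 genes with no run named for either; whether the libraries with no named run shared 1 run stays open. A wider set of active genes after TSA may remain as a hypothesis; a mixture of more cell types in these cultures was not tested.

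For the comparisons of 3 with 3 libraries, 10 splits are too few for a share under 0.05. The real split was in each case the 1 with as many calls. Every other split mixes libraries of both groups, which puts the group difference into the spread and lowers the calls. The gap between the real and the other splits is therefore no measure of the evidence. The real value and the highest other were 42701 and 0 for TSA at day 2, 43513 and 1 for TSA at day 4, 36294 and 0 for heat-only day 2 against day 0, 29185 and 0 for heat-only day 4 against day 2, and 4114 and 33 for TSA day 4 against day 2 (edgeR quasi-likelihood test). At an unadjusted p under 0.05 the highest other splits called 3142, 4781, 6186, 10259 and 5157 genes.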
